A study of Arabidopsis thaliana with 12 samples.

How the data were processed

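Small RNA libraries from shoots of A. thaliana Col-0 WT and hasty knockout seedlings, in a control and a low N condition, were analysed from one table with 12 library columns and 390 miRNA names. The labels describe the low N treatment and do not describe the control medium separately. As deposited, the values are whole-number counts per mature miRNA name, although the table is named TPM: the columns sum to between 1292752 and 3226269 and not to a common total. How the authors trimmed, aligned and counted the reads, with which versions, and how the 174 predicted names were found is not given in the sources used here. The processing notes of the submitters name only mm10, a mouse assembly, which cannot be the reference of these names. Coordinates here are from TAIR10.1, matched by the exact product name for 216 of 216 known names. The predicted names have neither sequence nor position here. In 31 sets, 64 names had identical values to another name, which left 357 distinct sets of values.

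The table total is the depth used here, and it counts reads listed under several names more than once, so it is not the sequencing depth. Libraries were amplified by PCR and the labels name no molecular identifiers, and replicate libraries differed by more than counting error. Zeros were kept as 0 and no limit of detection was computed from them. In 12 zero cells a name of identical sequence held 50 or more counts in the same library.

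Before the data were examined, the groups, contrasts, lists, naming rule and most alternatives were fixed. That plan used limma on log2(TPM + 1), with edgeR in its place if the table held counts, and edgeR was used for that reason. Names were filtered with filterByExpr, which kept 273, and fitted with edgeR 4.0.16 (TMM factors, glmQLFit, glmQLFTest, two-sided) in R 4.3.3 with 1 coefficient per group over all 12 libraries and 8 residual degrees of freedom. The 5 contrasts were hasty against WT in each nitrogen condition, low N against control in each genotype, and their interaction. Adjusted p-values are Benjamini-Hochberg over the names of a contrast with a threshold of 0.05. With 3 replicates per group they rest on a spread pooled over the 4 groups. Levels are TMM-normalised CPM, given as mean ± SD with n = 3. The SE beside a log2 change is the size of that change divided by the square root of its F statistic. It therefore restates the test and is no separate estimate of spread. The fitted change of a name at 0 throughout a group depends on the prior count and is no bound. None is given as a fold, and the closing section gives such values for the interaction of NovelmiRNA-70 and NovelmiRNA-66 alone.

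The 11 lists of families were low-nitrogen repressed and low-nitrogen induced in earlier work, copper-responsive, phosphate-responsive, juvenile phase, adult phase, auxin signalling, leaf development, small RNA machinery, secondary siRNA triggers and conserved families. Each list took all precursors and both arms of its families, so the counts of members include less abundant arms. Some lists share families. All copper-responsive families are also in the low-nitrogen-repressed list, so the tests of these lists are not independent. They were tested with camera of limma 3.58.1 on log2(CPM + 1), with a preset correlation of 0.01 and, as an alternative, an estimated one. Identical rows counted as 1 member in list counts and in camera, and adjustment was over the lists of a contrast. No marker list of cell types was used. Library summaries were compared by exact two-sided permutation of one factor within the other (400 assignments, smallest possible p = 0.005) with adjustment over 8 tests. An exact permutation test of 3 against 3 libraries cannot go below p = 0.10. Correlations of effects were computed across names and carry no p.

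Named miRNAs in a simple contrast were those past the threshold, with a mean of at least 10 CPM in the higher group and no overlap between the 3 libraries of either group: the 10 largest changes in each direction, with identical rows named together. The interaction gave the 5 smallest adjusted p in each direction, each list its 3 most abundant members, and the whole table its 10 most abundant names. After the data were seen, the first part was repeated on names above 0 in all 12 libraries, and 11 further names were added, which the results list.

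Alternatives fixed beforehand were pseudocounts of 0.1 and 10 (run with limma), no filter, a mean of at least 10 CPM, median-of-ratios size factors, quantile normalization, the most abundant miRNA left out, identical rows counted once, no abundance trend, a robust fit, only the groups compared, the replicate number as a block, and each library left out in turn. Each fit without 1 library was filtered again and tested 294 to 302 names in place of 273. A call lost there can therefore come from the names tested as well as from the library. Added after the data were seen were limma on log2(CPM + 1), DESeq2 1.42.0, library totals without TMM factors, only names above 0 in all 12 libraries, only known names, and each mature sequence counted once (as the median of its names above 0). Over names above 0 in all libraries, the median log2 change in the 5 contrasts (in the order above) was -0.17, -0.11, 0.09, -0.06 and -0.13 with TMM. It was -0.39, -0.06, -0.27, -0.15 and 0.14 with library totals and -0.05, 0.03, 0.13, 0.003 and -0.11 with median-of-ratios factors, so changes are relative to these medians.

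The labels number replicates 1 to 3 in each group. Residuals of libraries with the same number had a mean correlation of -0.036, so the libraries were not treated as paired. Counts were simulated with 1 dispersion, 0.052, the median over 167 names above 0 in all libraries, from which the changed names were also drawn. On these counts, 21 of 30 names changed by 1 on the log2 scale and 30 of 30 changed by 2 were called, with 0 of 201 unchanged names called. The common dispersion of the fit was 0.68, so these rates do not cover names of larger spread or with zeros. Tables and figures used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.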

Results

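Small RNA libraries listed by microRNA (miRNA) name were compared from shoots of Arabidopsis thaliana, ecotype Col-0, in wild type (WT) and in a hasty knockout, each in a control and in a low-nitrogen (low N) condition. HASTY (HST, AT3G05040, chromosome 3, positions 1401171 to 1408302, minus strand, TAIR10.1) is the plant orthologue of the nuclear export receptor exportin-5. Seedlings were harvested at 10 days, after 5 days of standard growth and 5 days of treatment, and each of the 4 groups had 3 biological replicates. The 2 × 2 layout asks which miRNAs differ between genotypes, which respond to low N, and whether the response depends on HASTY. The HST messenger RNA is not measured by these libraries, so the knockout was taken from the labels.

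The table held whole-number counts for 390 names, of which 216 were known A. thaliana miRNAs (written here without the prefix ath-) and 174 were predicted names numbered as NovelmiRNA. The counts listed per library summed to 3078190 ± 233803 (SD, n = 3) in WT control, 2126307 ± 189483 in hasty control, 2429809 ± 121358 in WT low N and 1555256 ± 241451 in hasty low N, with a range of 1292752 to 3226269. Members of the miR165 and miR166 families, which act on HD-ZIP III leaf polarity genes, took 54.8% ± 3.3 (SD, n = 3) of the listed counts in WT control and 64.3% ± 1.8 in hasty control. In low N the values were 59.3% ± 3.2 in WT and 66.5% ± 2.7 in hasty. The 7 miR166 names of one mature sequence held similar counts in each library, so these shares list that sequence under 7 names. With one mature sequence counted once they were 19.5% ± 2.3, 27.2% ± 1.5, 22.7% ± 2.5 and 29.0% ± 2.5, in the same order of groups. The 10 highest names held 68.5% ± 0.76 of counts in WT control, 74.4% ± 0.93 in hasty control, 72.8% ± 0.80 in WT low N and 75.0% ± 2.1 in hasty low N. This share was 4.11 percentage points higher in hasty (two-sided exact permutation within nitrogen conditions, p = 0.010, adjusted over 8 tests p = 0.020) and 2.44 points higher in low N (permutation within genotypes, p = 0.035, adjusted p = 0.040). With one mature sequence counted once the difference was 0.043 points by genotype (exact permutation p = 0.965) and 2.81 points by nitrogen (p = 0.010, exact permutation). Besides the miR166 names, the most abundant were miR159a at 59716 ± 11685 TMM-normalised CPM (counts scaled to 1000000 per library) in WT control and miR159b-3p at 41180 ± 8000. The number of names at 1 CPM or more was 10 lower in hasty (exact permutation p = 0.030, adjusted p = 0.040) and 11 lower in low N (p = 0.020, adjusted p = 0.032). The table totals differed by -913218 counts in hasty and by -609716 in low N (exact permutation p = 0.005 for both, the smallest possible, adjusted p = 0.020). The difference in names by genotype was 0.0 at a minimum of 10 CPM (exact permutation p = 1.0) and -8.33 without WT control replicate 3 or without hasty control replicate 1 (p = 0.055). The share of the 10 highest names in low N had an exact permutation p of 0.050 to 0.075 without 1 of hasty control replicate 1 or 2, WT low N replicate 2 or 3, or hasty low N replicate 1 or 2. Mean log2(CPM + 1) was 0.21 lower in low N (exact permutation p = 0.010, adjusted p = 0.020), and its difference of -0.09 by genotype missed the threshold (p = 0.085, but -0.12 and p = 0.020 without hasty low N replicate 3, and -0.0092 and p = 0.88 with one mature sequence counted once). Totals of the table are not sequencing depth, so all changes below are relative to the other listed miRNAs.

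Of the 390 names, 222 were listed at 0 in 1 or more libraries, in 64 cases with 50 or more counts in both other libraries of the group. A 0 is therefore written as "listed at 0", and names at 0 throughout a group are given by their counts, or the range of these, with no fold change. The clearest case was miR319b (chromosome 5, positions 16660469 to 16660489), listed at 0 in all 6 WT libraries and at 1121 to 1684 counts in all 6 hasty libraries. The name miR319a, which has the identical 21-nt sequence UUGGACUGAAGGGAGCUCCCU, held 1440 to 2172 counts in those WT libraries. When the names of one mature sequence were counted once, miR319 differed by 0.16 (log2) between genotypes in control, adjusted p = 0.31, and by 0.27 in low N, adjusted p = 0.077, so the edgeR calls for miR319b rested on its listing.

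In control conditions, hasty shoots held 4.43-fold more miR393b-3p, 3.3-fold more miR396b-3p and 2.40-fold more miR157a-5p and miR157b-5p than WT, while miR403-3p, miR827, miR397b and miR156f-3p were 2.89-fold to 4.84-fold lower. The miR157 names, which repress the SPL genes that promote the adult phase, rose from 2273 ± 369 to 5460 ± 378 CPM (SD, n = 3), a log2 change of 1.26 ± 0.11 (SE), edgeR adjusted p = 1.8e-05. The arm miR393b-3p rose from 393.6 ± 136 to 1745 ± 89.8 CPM. Among the lower names, miR403-3p, which targets AGO2, fell from 446 ± 31.7 to 154 ± 16.2 CPM (log2 change -1.53 ± 0.10, adjusted p = 2.7e-06). In the same direction, miR168a-5p, which targets AGO1, went from 10618 ± 586 to 5329 ± 672 CPM (-0.99 ± 0.10, adjusted p = 3.1e-05). The abundant miR159b-3p, which acts on GAMYB-like genes, fell from 41180 ± 8000 to 19688 ± 465 CPM (-1.06 ± 0.16, adjusted p = 0.00072).

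In all, 125 of 273 tested names passed an adjusted p of 0.05 in edgeR's quasi-likelihood test between hasty and WT in control, 51 higher and 74 lower. Other higher names were miR824-5p (2.22-fold), which targets AGL16, and miR858a (2.14-fold), which targets MYB genes. The deepest fall among such names was that of miR781a, from 61.1 ± 16.1 to 5.02 ± 2.29 CPM (12.1-fold, adjusted p = 0.00019). This miRNA lies on chromosome 1 at 7423523 to 7423543, inside the coding gene AT1G21200 on the same strand. The phosphate-linked miR827 (chromosome 3, 22122811 to 22122831), which targets NLA, fell from 206 ± 43.3 to 65.2 ± 10.7 CPM (adjusted p = 0.00013). The laccase regulator miR397b (chromosome 4, 7878730 to 7878750) fell from 726 ± 76.4 to 253 ± 37.9 CPM (adjusted p = 4.4e-05). The name miR847 (chromosome 1, 2165675 to 2165695), which targets IAA28, was listed at 1976, 1008 and 1161 counts in WT control, at 132, 132 and 210 in WT low N and at 0 in all 6 hasty libraries. Conversely, miR848 was listed at 0 in all WT libraries and at 138, 128 and 178 counts in hasty control (adjusted p = 0.019, and 0.080 with the replicate number as a block). It was also listed at 0 in hasty low N replicate 3, where both other libraries of the group held 82 or more counts. The name miR2934-5p was listed at 0 in WT and at 32, 51 and 34 in hasty control. The predicted names NovelmiRNA-154 and NovelmiRNA-155 were listed at 68 to 105 counts in WT and at 0 in hasty, and NovelmiRNA-35 at 0 in WT and at 29 to 52 in hasty. The level of miR840-5p was 0.54 ± 0.47 CPM in WT control and 12.3 ± 1.87 in hasty control (adjusted p = 0.0066).

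By list, the small RNA machinery families (miR162, miR168 and miR403, which target DCL1, AGO1 and AGO2) had 6 of 10 members lower and 2 higher in hasty control, the same counts when adjusted over the list alone. All lists hold both arms, so these 10 members include the less abundant arms miR162a-5p, miR168a-3p, miR168b-3p and miR403-5p. Which arm acts on the targets was not tested. The members were of 7 mature sequences, 5 lower and 1 higher. The 2 higher members, miR162a-3p and miR162b-3p, are of one mature sequence and changed by 0.37 and 0.36 (log2), adjusted p = 0.0025 and 0.0026, and were no longer called with library totals in place of TMM factors. The juvenile-phase list (miR156 and miR157) had 3 of 18 members higher and 9 lower, also 3 and 9 over the list alone, or 2 higher and 5 lower of 12 mature sequences. The higher ones were the 5p arms of miR157a with miR157b and of miR157c, and miR156b-3p, from 8231 ± 264 to 11790 ± 570 CPM (adjusted p = 0.00016). Its lower members included miR156c-3p, from 3151 ± 372 to 1312 ± 143 CPM (adjusted p = 2.2e-05). Leaf development families had 15 of 27 members higher and 9 lower (15 and 9 adjusted over the list alone), where the 15 were of 7 mature sequences and included 7 names of the one miR166 sequence and miR319b, and the 9 were of 8. The miR166 names differed by 0.44 to 0.46 (log2), and quantile normalization ended these calls and turned the sign for 3 of the names (miR166e-3p, miR166f and miR166g). Of 17 auxin-signalling members 4, of 3 mature sequences, were higher and 1 lower (4 and 1 over the list alone). The arm miR167a-3p fell from 17038 ± 1224 to 6315 ± 861 CPM, while miR167a-5p, the ARF6 and ARF8 regulator, stood at 36048 ± 6337 and 39139 ± 1826 CPM (adjusted p = 0.54). Limma's camera test called none of the 11 lists in this contrast. The smallest adjusted p was 0.33, 1 list had an unadjusted p under 0.05, and with an estimated correlation the smallest adjusted p was 0.70. For leaf development the median of 0.45 and the mean of -0.003 over members above 0 in all libraries differed in sign. The split of single calls depended on the scaling: 36 were higher and 81 lower with library totals, 63 and 67 with median-of-ratios factors, and 74 and 69 in DESeq2.

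**Figure D1:**
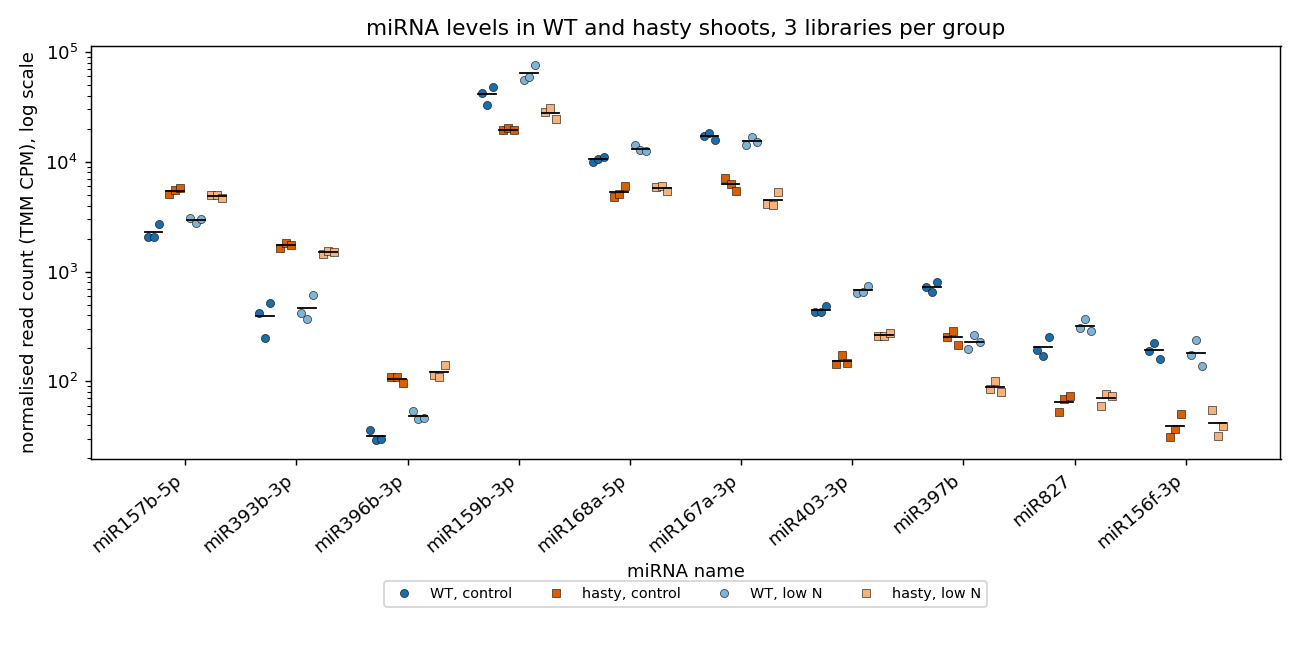
Normalised read counts (TMM CPM, log axis) of 10 miRNA names in each library, with circles for WT, squares for hasty and a black line at the mean of the 3 libraries of a group. For miR157b-5p, miR393b-3p and miR396b-3p all hasty libraries lie above the WT libraries of the same condition, and for the other names below them, as for miR403-3p at 154 and 446 CPM in control.

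Under low N, miR393b-3p was 3.22-fold and miR396b-3p 2.5-fold higher in hasty, and miR827 was 4.56-fold, miR156f-3p 4.38-fold and miR167a-3p 3.43-fold lower. Levels of miR827 were 321 ± 44.0 CPM in WT low N and 70.3 ± 9.25 in hasty low N (SD, n = 3), a log2 change of -2.19 ± 0.20 (SE), edgeR adjusted p = 2e-05. The arm miR167a-3p (chromosome 3, 8108172 to 8108192) fell from 15366 ± 1377 to 4486 ± 689 CPM (-1.78 ± 0.13, adjusted p = 7.1e-06). Among higher names outside these, miR169a-5p, of the family that acts on NF-YA genes, rose from 44.5 ± 7.57 to 99.1 ± 9.65 CPM (2.23-fold, adjusted p = 0.00036). Of 273 names, 95 passed the threshold, 31 higher and 64 lower.

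Among names of the repeated rule, miR156c-3p, miR398a-3p, miR397b and miR403-3p were 2.76-fold, 2.64-fold, 2.60-fold and 2.55-fold lower in hasty low N, and miR824-5p was 1.77-fold higher. The predicted name NovelmiRNA-171 fell from 51.6 ± 3.68 to 9.26 ± 3.46 CPM (adjusted p = 0.00013). Several names were separated by listing: miR173-5p, a trigger of secondary siRNAs, was listed at 227, 240 and 244 counts in hasty low N and at 0 in WT low N, but also at 0 in 1 WT control library whose sisters held 355 and 314. The phosphate-linked miR399f was listed at 63, 77 and 48 counts in WT low N and at 0 in hasty low N, and miR853 at 31, 37 and 29 against 0. NovelmiRNA-162 was listed only in hasty low N, at 1018, 1107 and 1007 counts, and NovelmiRNA-70 at 2279, 1946 and 2362 counts in WT low N and at 0 in hasty low N. In the lists, which hold both arms, small RNA machinery had 7 of 10 members lower and 0 higher (7 lower and 2 higher adjusted over the list alone). The 7 were of 6 mature sequences, with miR168a-5p at 13175 ± 1048 and 5806 ± 327 CPM. The juvenile phase had 12 of 18 lower and 3 higher (12 and 3 over the list alone), or 7 and 2 of 12 mature sequences, with miR157b-5p higher at 0.73 (log2, adjusted p = 0.00046) and the identical miR157a-3p and miR157b-3p lower at -1.30 (adjusted p = 1.1e-05). The phosphate-responsive families had 4 of 7 lower (4 over the list alone), namely miR827, miR399f, and miR399b with miR399c-3p of one mature sequence, or 3 of 6 mature sequences. Without a filter on low counts miR399b and miR399c-3p had adjusted p = 0.10 and 0.082. Copper-responsive families had 3 of 8 lower (3 over the list alone), while the abundant miR398b-3p, which targets Cu/Zn superoxide dismutases, stood at 2743 ± 255 and 2829 ± 257 CPM (adjusted p = 0.82).

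Camera called none of the 11 lists here, with 4 at an unadjusted p under 0.05: small RNA machinery and juvenile phase both had adjusted p = 0.0501 (0.61 with an estimated correlation). The number of called lists was 3 without hasty control replicate 1 and 1 without WT low N replicate 2 or without hasty low N replicate 3. With median-of-ratios size factors the calls of single names split into 47 higher and 59 lower, and DESeq2 called 73 higher and 70 lower.

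Across all 273 names the hasty effects in control and in low N, which share no libraries, had a Spearman correlation of 0.75 and a Pearson correlation of 0.55. Without the 106 tested names listed at 0 in 1 or more libraries these were 0.80 and 0.81. In both conditions 26 names were higher, where 5.79 would be expected from independent lists (Fisher's exact test, p = 1.6e-17). In both, 49 were lower, where 17.3 would be expected (p = 2.4e-22, Fisher's exact test), and 0 were called in opposite directions. These are comparisons across names, which are not independent replicates, since many share reads. Both contrasts also use 1 spread estimate per name, so the lists are not independent. Without any 1 library the Spearman value was lower, at 0.56 to 0.69. It was 0.56 to 0.62 without 1 of hasty control replicate 2, WT low N replicate 3, hasty low N replicate 1 or hasty low N replicate 3. These fits were filtered again and tested 294 to 302 names, so the drop can come from the added names as well as from the library.

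**Figure D2:**
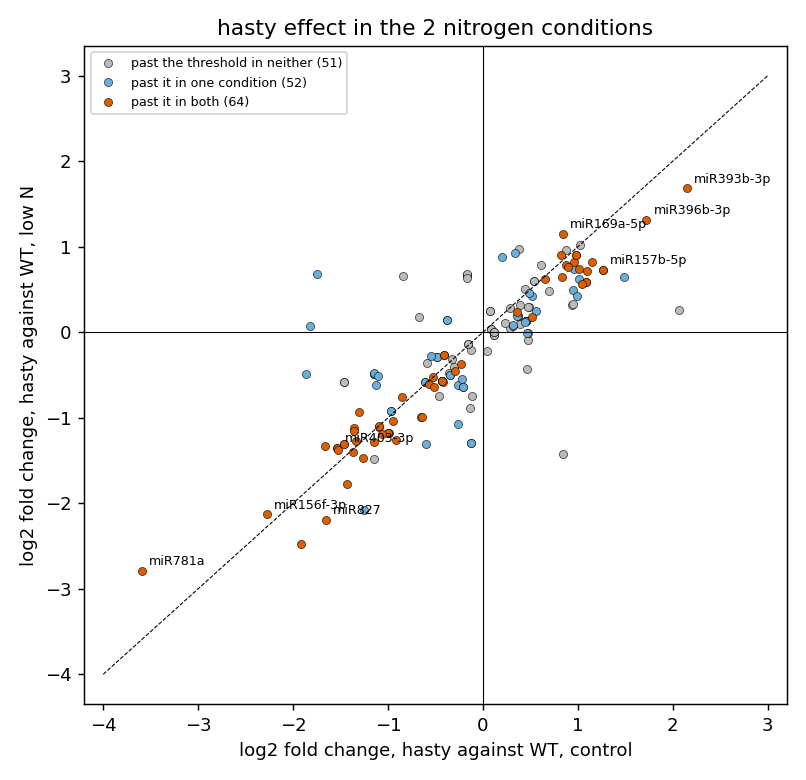
Log2 fold change of hasty against WT in control (horizontal axis) and in low N (vertical axis) for tested names above 0 in all 12 libraries, coloured by whether they passed an adjusted p of 0.05, with a dashed line of equal effects. Points run along that line, from miR781a at -3.59 and -2.79 to miR393b-3p at 2.15 and 1.69. In low N miR781a was of low level already in WT, so its change there rests on few counts.

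In WT shoots under low N, miR395b and miR395c, which act on ATP sulfurylases, fell 11.2-fold, miR169k 4.46-fold, miR397b 3.15-fold and miR398b-3p 2.28-fold. Levels of miR395b and miR395c, whose rows are identical, went from 81.0 ± 5.71 to 7.18 ± 4.08 CPM (SD, n = 3), a log2 change of -3.49 ± 0.65 (SE), edgeR adjusted p = 0.0028. The abundant miR398b-3p and miR398c-3p fell from 6258 ± 605 to 2743 ± 255 CPM (-1.19 ± 0.10, adjusted p = 5.2e-05). Rising names included miR824-5p (2.5-fold), miR167c-3p (2.40-fold), miR165a-3p (2.16-fold), miR164c-5p (2.11-fold), which targets CUC-type NAC genes, and miR842 (2.04-fold). Of 273 names, 88 passed the threshold, 47 higher and 41 lower.

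Among names of low level, miR156h rose from 1.37 ± 0.75 to 11.3 ± 3.97 CPM (adjusted p = 0.0088), and miR839-5p rose 2.28-fold. The identical predicted names NovelmiRNA-14 and NovelmiRNA-15 rose 3.79-fold, to 1027 ± 139 CPM. NovelmiRNA-166 was listed at 0 in all 6 control libraries and at 371 to 693 counts in all 6 low N libraries, and NovelmiRNA-60 at 28 to 56 counts in control and at 0 in low N. NovelmiRNA-66 fell from 108 ± 7.91 to 5.75 ± 2.85 CPM (adjusted p = 0.00038). The miR781a level fell 7.36-fold to 8.25 ± 1.10 CPM (adjusted p = 0.00085).

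The 7 names miR169h to miR169n have the single mature sequence UAGCCAAGGAUGACUUGCCUG, and all 7 passed the threshold downward in WT. The values of miR169j, miR169k, miR169m and miR169n were close in every library (428 to 466 counts in WT control, 50 to 73 in WT low N). In WT control, miR169h, miR169i and miR169l instead held 1038 to 1465 counts, and in the hasty libraries they held 44 to 276 counts, the same range as the other 4 names. The fall of this sequence is therefore given by miR169k (chromosome 3, 9875675 to 9875695), at 122 ± 6.97 and 27.3 ± 6.06 CPM and a log2 change of -2.16 ± 0.30 (adjusted p = 0.00045), and not by miR169h at -3.73.

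The families reported as repressed by low nitrogen in earlier work had 14 of 34 members lower and 1 higher, or 15 and 2 adjusted over the list alone. The 14 were of 8 mature sequences, and miR169h to miR169n, one sequence, gave 6 of them (identical rows counted once). The higher one was miR827 at 0.64 (log2, adjusted p = 0.027), no longer called without 1 of WT control replicate 1 or 2 or WT low N replicate 1 or 2 (adjusted p = 0.064 to 0.093). The camera test of the low-nitrogen-repressed families gave adjusted p = 4e-06, 0.0096 with an estimated correlation, and 0.0032 with one mature sequence counted once. The copper-responsive families had 7 of 8 lower, of 6 mature sequences (7 over the list alone), camera adjusted p = 3.5e-05 and 0.023 with an estimated correlation. All of them are part of the low-nitrogen-repressed list, so both results rest partly on the same members. Copper-responsive families were lower with each scaling tried, the medians lying between -1.29 and -1.69. Leaf development families had 17 of 27 members higher and 0 lower (18 and 1 over the list alone). The 17 were of 9 mature sequences and included the 7 names of one miR166 sequence. The median of the leaf development list was 0.45 (log2), but 0.087 with library totals and 0.00014 with quantile normalization. Their camera adjusted p was 2.4e-05, but adjusted p = 0.16 with an estimated correlation, 0.29 with quantile normalization and 0.046 with one mature sequence counted once. Examples were miR164c-5p, from 464 ± 1.34 to 979 ± 79.3 CPM (adjusted p = 0.00010), and miR165a-3p, from 8307 ± 1029 to 17951 ± 2359 CPM (adjusted p = 0.00029). Of the families reported as induced by low nitrogen in earlier work 1 of 7 members was higher, miR842, from 335 ± 21 to 682 ± 42.4 CPM (1 over the list alone, camera adjusted p = 0.43). The auxin-signalling list had 3 of 17 higher, among them miR167c-5p and miR167c-3p (camera adjusted p = 0.43), and the juvenile phase 6 of 18 higher, of 4 mature sequences, and 2 lower (adjusted p = 0.25). The split of single calls depended on the scaling: with library totals in place of TMM factors 15 names were higher and 62 lower, where the median of all names above 0 in every library lay at -0.27 instead of 0.09 (log2). With quantile normalization 39 were higher and 50 lower, and with one mature sequence counted once 21 and 36.

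In hasty shoots under low N, miR395b and miR395c fell 6.13-fold, miR157c-3p 3.10-fold, miR397b 2.85-fold and miR398b-3p 2.34-fold. Among rising names, miR824-5p rose 1.99-fold, miR167c-3p 1.94-fold, miR164c-5p 1.93-fold and miR842 1.86-fold. The level of miR398b-3p went from 6621 ± 475 to 2829 ± 257 CPM (SD, n = 3), a log2 change of -1.23 ± 0.10 (SE), edgeR adjusted p = 3.3e-05, and that of miR397b from 253 ± 37.9 to 88.6 ± 10.8 CPM (adjusted p = 0.00011). The AGO2 regulator miR403-3p rose from 154 ± 16.2 to 267 ± 9.10 CPM (adjusted p = 0.00022). Of 273 names, 65 passed the threshold, 24 higher and 41 lower.

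Further risers were miR156h, from 1.83 ± 1.40 to 12.1 ± 1.47 CPM (adjusted p = 0.019, but 0.068 to 0.080 without 1 of hasty control replicate 1 or 2 or hasty low N replicate 1 or 2) and NovelmiRNA-14 with NovelmiRNA-15 (3.92-fold). NovelmiRNA-70 was listed at 2082, 2347 and 1542 counts in hasty control and at 0 in hasty low N, and NovelmiRNA-100 at 136, 192 and 136 against 0. The low-nitrogen-repressed families had 17 of 34 members lower, of 10 mature sequences, and 0 higher (19 and 1 over the list alone), camera adjusted p = 1.5e-05, and 0.013 with an estimated correlation. Copper-responsive families, all part of the list just named, had 7 of 8 lower, of 6 mature sequences (8 over the list alone), adjusted p = 3.8e-05, and 0.023 with an estimated correlation. Leaf development families had 8 of 27 higher, of 6 mature sequences (9 over the list alone), adjusted p = 2.7e-05, but adjusted p = 0.17 with an estimated correlation. The phosphate-responsive list had 3 of 7 lower, of 2 mature sequences (3 over the list alone), miR399c-3p at -0.62 (log2, adjusted p = 0.020, and 0.081 with only the groups compared) among them, with camera adjusted p = 0.26. Without hasty low N replicate 2 the number of called names was 41 in place of 65, and with quantile normalization the split was 39 higher and 40 lower.

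**Figure D3:**
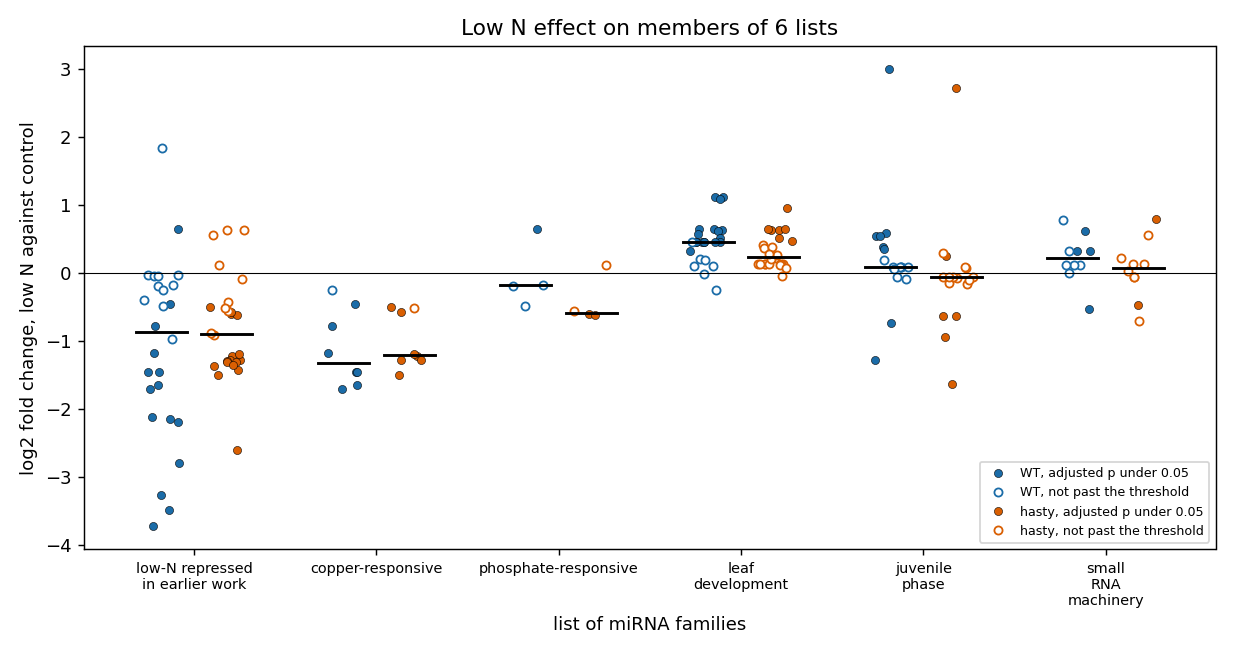
Log2 fold change of low N against control in WT (blue) and hasty (orange) for members above 0 in all 12 libraries of 6 lists of miRNA families, with filled points past an adjusted p of 0.05 and black lines at the medians. The copper-responsive medians lie at -1.33 in WT and -1.21 in hasty, and the leaf development medians at 0.45 and 0.24, but at 0.00014 to 0.49 and 0.15 to 0.30 over the scalings tried.

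The low N effects in WT and in hasty had a Spearman correlation of 0.62 and a Pearson correlation of 0.42 across the 273 names, and of 0.76 and 0.85 over the names above 0 in all libraries. Both genotypes shared 22 names higher, with 4.13 expected from independent lists, and 29 lower, with 6.16 expected (Fisher's exact test across names, p = 2.3e-17 and 3.2e-20). Here too, many names share reads and both contrasts use 1 spread estimate per name. The lists are therefore not independent, and these p-values are no measure of replication. The 2 names called in opposite directions were miR157a-3p and miR157b-3p, whose rise in WT (0.54, log2) was no longer called without 1 of WT control replicate 1 or 3 or any 1 of the hasty control or WT low N libraries (adjusted p = 0.051 to 0.11). Nor was it called without the filter (adjusted p = 0.084) or with library totals in place of TMM factors (adjusted p = 0.49). Without any 1 library the Spearman value was lower, at 0.46 to 0.60. It was 0.46 to 0.49 without 1 of hasty control replicate 1, hasty control replicate 2, WT low N replicate 3 or hasty low N replicate 1. These fits tested 294 to 302 names after a new filter, so the drop can come from the added names as well as from the library.

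The response to low N differed by genotype for miR157a-3p and miR157b-3p, which share one sequence: both went from 2661 ± 104 to 3867 ± 326 CPM in WT and from 2444 ± 62.0 to 1576 ± 264 CPM in hasty (SD, n = 3). Their interaction, the hasty effect in low N minus that in control, was -1.17 ± 0.15 (log2, SE), edgeR adjusted p = 0.0022. It was not called without 1 of WT control replicate 2, hasty control replicate 1, 2 or 3, or hasty low N replicate 1 or 2 (adjusted p = 0.051 to 0.075), nor without the filter (adjusted p = 0.056) or with library totals in place of TMM factors (adjusted p = 0.19). With 3 other names, 5 of 273 were called, 1 higher and 4 lower. NovelmiRNA-70, listed at 4823, 4683 and 5685 counts in WT control and above 0 in all groups except hasty low N, was called lower (adjusted p = 6.3e-08, at most 1.7e-05 under every alternative that tested it). These alternatives all reuse the hasty low N cells listed at 0, so they cannot tell an absence of reads from a name left out of the list. NovelmiRNA-66, which held 51, 87 and 91 counts in hasty control and was listed at 0 in hasty low N, was also called lower (adjusted p = 0.014, but 0.057 to 0.094 without 1 of WT control replicate 2, hasty control replicate 2 or any hasty low N library). The fitted NovelmiRNA-66 interaction depends on the prior count, since a whole group was at 0, and was positive and not called with pseudocount 10 (adjusted p = 0.24). It was not called with quantile normalization, limma on log2(CPM + 1) or the replicate block either (adjusted p = 0.31, 0.34 and 0.058). The interaction of miR169h was 2.42 ± 0.42 (adjusted p = 0.014). The adjusted p was 0.052 to 0.095 without 1 of WT control replicate 2, any hasty control library, WT low N replicate 2 or 3, or hasty low N replicate 2, and 0.058 for miR169h with the replicate block. The value rested on WT counts that 4 other names of the same sequence did not show, and miR169k gave 0.85 ± 0.41 (adjusted p = 0.45).

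None of the 11 lists was called for the interaction by camera. The juvenile phase came nearest, at adjusted p = 0.051 and 0.52 with an estimated correlation, with 2 of 18 members, of 1 mature sequence, lower, or 5 over the list alone, and 2 lists had an unadjusted p under 0.05. The count of 5 names was 1 without WT control replicate 2, hasty control replicate 2 or hasty low N replicate 2. It was 3 without hasty control replicate 3 or hasty low N replicate 1, and 8, 11, 9 and 8 without WT control replicate 1, WT control replicate 3, WT low N replicate 1 and WT low N replicate 2. It was 15, with 9 higher, after quantile normalization, 3 higher and 2 lower with library totals, and 25, with 9 higher, in DESeq2.

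**Figure D4:**
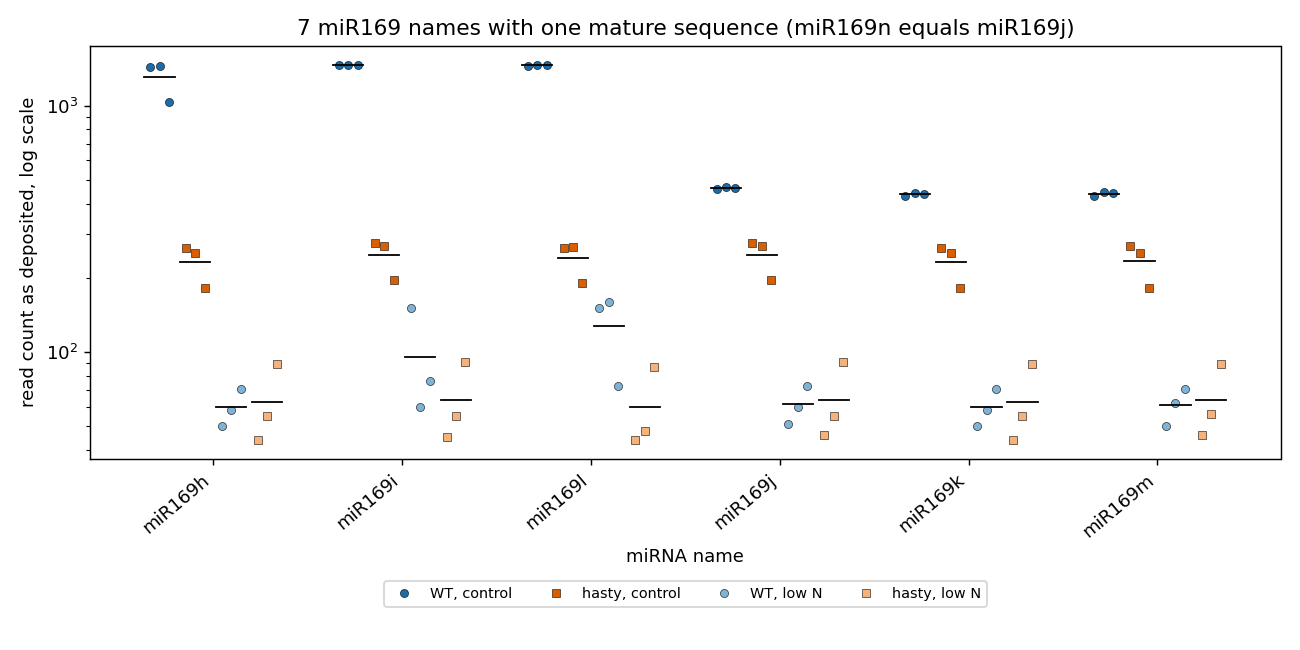
Deposited read counts (log axis) of 6 miR169 names with one mature sequence in each library, circles for WT and squares for hasty, with black lines at group means. In WT control miR169h, miR169i and miR169l lie at 1038 to 1465 counts and the other names at 428 to 466, while the hasty libraries of all names overlap.

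The remaining lists passed the camera test in no contrast. For the adult phase (miR172) 1 of 4 members was higher in hasty control, miR172b-3p at 9.89 ± 4.90 against 3.50 ± 1.27 CPM (adjusted p = 0.025, but 0.050 to 0.13 without 1 of WT control replicate 1 or 2 or hasty control replicate 3), and 0 of 4 were called in the other contrasts, with camera adjusted p from 0.54 to 0.97. Secondary siRNA triggers had 2 of 8 higher in hasty low N and 2 of 8 lower in WT under low N. In both cases these were miR173-5p and miR173-3p, listed at 0 in WT low N. The fall of miR173-3p was not called without 1 of WT control replicate 2 or WT low N replicate 1 or 2 (adjusted p = 0.053 to 0.059), and that of miR173-5p not with the replicate block (adjusted p = 0.059). The list had camera adjusted p from 0.19 to 0.76. In this list miR161.1, at 13675 ± 2220 CPM in WT control and 10913 ± 882 in hasty control, did not pass (adjusted p = 0.062). The broad list of conserved families had 26 of 120 members higher and 40 lower in hasty control (15 and 28 of 82 mature sequences) and 9 higher and 41 lower in hasty low N (7 and 31), with camera adjusted p from 0.0997 to 0.65 over the contrasts. In the lists not named above for a contrast, the camera adjusted p was 0.25 to 0.97 for auxin signalling and 0.34 to 0.97 for the low-nitrogen-induced families. The median and mean of a list over members above 0 in all libraries and the direction of its camera test did not all have one sign in 12 cases, none of them called. These were low-nitrogen-induced families in hasty control and in hasty under low N, adult phase and auxin signalling in hasty low N and in hasty under low N, and leaf development in both hasty contrasts. The others were secondary siRNA triggers in both hasty contrasts and in WT under low N, and conserved families in WT under low N. Outside the naming rule, and chosen after their values were seen, were miR156c-3p and miR162a-3p in hasty control, miR157a-3p and miR781a in hasty low N, miR397b, miR842, miR164c-5p, miR167c-5p, miR157a-3p, miR173-5p and miR173-3p in WT under low N, miR157a-3p in hasty under low N, and miR169k in the interaction.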

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

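All tests on the zeros, on miR169, on the arms and on other splits of the libraries were chosen after the results were seen. The interaction test singled out 5 names whose low N response differed between WT and hasty (log2). The values were -1.17 for miR157a-3p and -1.17 for miR157b-3p, which have one sequence, -13.57 for NovelmiRNA-70, 2.42 for miR169h and -5.19 for NovelmiRNA-66. The fitted values of both predicted names depend on the prior count, since they were listed at 0 in all hasty low N libraries, and are no bound. Of 100 splits drawn, 1, the real one, gave as many calls as the 5 found, and the highest of the others gave 3. The others mix both genotypes and both nitrogen conditions within a group, so that the differences between these enter their residual spread: the common dispersion was 0.68 in the real split and 1.01 to 1.61 in the others. These splits therefore do not show whether chance can be excluded. Without 1 library the count was 1 to 11.

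For the simple contrasts the 10 splits of 3 against 3 libraries are too few for a share under 0.05. The other splits also mix libraries of both groups compared, so that the difference between the groups enters the residual spread and lowers their calls. Their counts below therefore do not show what chance alone would give. The real split, the 1 of 10 with as many calls in each contrast, gave 125 names for hasty in control with 2 as the highest other, 95 with 7 for hasty in low N, 88 with 4 for low N in WT, and 65 with 3 for low N in hasty.

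Abundant names listed at 0 were the first pattern weighed. In 64 cells, over 49 names, a name was at 0 while both other libraries of its group held 50 or more counts. Counting error alone would give 1.3e-20 such cells, and the highest dispersion among names above 0 in all libraries 0.10. Too few sampled reads are therefore argued against at spreads up to that dispersion, 0.43. Names with zeros did not enter it, and the common dispersion of the fit was 0.68, so larger spreads are not covered. In 12 of 76 testable zero cells (15.8%, 4 names, miR319b among them) a name with the identical sequence held 50 or more counts in that library. In these cells the 0 does not show an absence of the sequence. The share was below that set for names left out of a library's list, so for the other zero cells this explanation stays open. In some cases both arms of a precursor were at 0 in the same library. In hasty control replicate 3 these were miR822-3p and miR822-5p, where the lower of the other libraries held 5071 and 3868 counts. In hasty control replicate 1, miR390b-3p stood at 0 with miR390b-5p, whose sequence held 1049 counts under miR390a-5p. Such pairs were not counted over all precursors, and their bearing on omission was not tested. Of 462 splits of the 12 libraries into 6 and 6, 1, the real one by genotype, had as many as 8 names at 0 throughout one side and above 0 throughout the other, and the highest other had 2, which argues against omission at random with regard to genotype. For miR319b, 1 of the 8, the zeros stood beside 1440 to 2172 counts of the identical sequence under miR319a and so do not show its absence. For the other 7 names a loss or gain in hasty and an omission that follows genotype stay open. Among them miR830-5p and miR830-3p held only 3 to 17 and 1 to 15 counts in the WT libraries. At such low counts their zeros in hasty do not show a full loss.

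The excess of miR169h, miR169i and miR169l over 4 names of the same sequence was the second pattern. Reads of these loci produced in every WT library are argued against, as 0 of 3 names showed the excess in all 6 WT libraries. Production in part of them stays open and cannot be tested here, since reads of the shared mature sequence do not tell the loci apart. A candidate explanation that also stays open is values that are not read counts of the sequence, such as an added digit: 9 of the 12 exceeding cells lay within 3 counts of another member plus 100 or 1000, as with 1428 beside 428. These steps were picked after the equalities were seen, so the count restates them and tests nothing. All 12 cells were WT libraries, so the miR169h interaction may come from these values.

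The third pattern was the ratio of the less abundant to the more abundant arm of a precursor. Its median over 36 precursors differed between hasty and WT by -0.27 (log2, exact permutation p = 0.010, adjusted p = 0.030) and was lower in 21 of 36. The adjustment was made together with the tests of classes below, which were chosen beforehand. Low counts are argued against, since the difference was -0.45 (exact permutation p = 0.005, the smallest possible) among 17 precursors whose lesser arm averaged 200 or more counts. Reads listed under several precursors stay open: among 8 precursors with no shared arm sequence the difference was 0.060 (exact permutation p = 0.64, lower in 3). A lower arm ratio in hasty may therefore be a matter of shared reads.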

How the results depend on the processing

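Limma on log2(CPM + 1), DESeq2, library totals, only names above 0 in all libraries, only known names and one sequence counted once were chosen after the data were seen. Of 193 calls of named miRNAs, 113 kept direction and threshold under every alternative that tested them. Over 5615 alternative values 5146 did, 456 missed the threshold and 13 reversed. The cause was not tested except where said.

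The count of called miRNAs was 143 for hasty in low N and 98 for low N in hasty with DESeq2, and 57 for low N in WT with one sequence counted once, which tests fewer names. For the interaction it was 14 and 16 with pseudocounts 0.1 and 10, 15 with quantile normalization, 11 without the most abundant miRNA, 13 with limma, 25 with DESeq2 and 3 with the replicate block. The replicate block gave 101, 83, 72 and 51 in the simple contrasts. Called lists for hasty in low N were 2 with pseudocount 0.1, pseudocount 10 or the replicate block. For the interaction they were 1 with pseudocount 10, a mean of 10 CPM, median-of-ratios factors or the replicate block, and 2 without the most abundant miRNA or with only names above 0 in all libraries.

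Leaving out 1 library, the counts were 104 to 125, 81 to 102, 66 to 89, 41 to 80 and 1 to 11, and called lists 0 to 0, 0 to 3, 3 to 3, 3 to 4 and 0 to 2, in the order of the contrasts. The effect correlations were 0.56 to 0.69 (hasty) and 0.46 to 0.60 (low N), the latter 0.76 with only names above 0 in all libraries. Names detected by genotype differed by -11.6 to -8.33, and by 0.0 at 10 CPM. The top share by genotype was 3.67 to 4.69, 1.07 for the top 20 (p = 0.050, exact permutation) and 0.043 with one mature sequence counted once. By nitrogen it was 2.0 to 3.03, and 0.51 for the top 1. Mean log2 level by genotype was -0.12 to -0.075, -0.18 with pseudocount 0.1 and -0.0092 with one mature sequence counted once (exact permutation p = 0.88). Names detected by nitrogen were -12.7 to -9.33, and mean log2 level by nitrogen -0.24 to -0.20.

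Signs reversed with quantile normalization, which by construction gives the top ranks one value, for hasty in control at -0.0056 (miR166e-3p), -0.00048 (miR166f) and -4.7e-05 (miR166g). For low N in WT they were -4.0e-06 (miR166c), -3.2e-05 (miR166e-3p), -0.00024 (miR166f), -0.15 (miR166g) and -0.11 (miR168a-5p), and for low N in hasty -0.14 (miR156b-3p). With library totals, low N in WT gave -0.047 for miR168a-5p, -0.047 for miR168b-5p and -0.0027 for miR157c-5p. The interaction of NovelmiRNA-66, a fitted value over a group listed at 0 that is no bound, was 0.75 with pseudocount 10. Robust fits and identical rows counted once were not run for the lists. The simulation used the table totals and 1 dispersion, that of names above 0 in all libraries, and did not vary depth. What depth alone limits is therefore not known. In the simulation, names changed by 1 (log2) were called in 21 of 30 cases.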

Other observations

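The 3 tests of classes in this part were chosen before their results were seen, and the names in the first paragraph after. Adjusted p-values of the class tests were computed together with the arm-ratio test above, which was chosen after the results were seen. In hasty control miR839-5p rose from 37.9 ± 9.13 to 76.6 ± 22.4 CPM (SD, n = 3, edgeR adjusted p = 0.0070). The name miR822-3p was listed at 0 in hasty control replicate 3, where the lower of the other libraries of the group held 5071 counts, and was not called (adjusted p = 0.60).

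By length, the 7 known miRNAs of 22 nt above 0 in all libraries (miR156a-3p, miR156c-3p, miR162a-5p, miR393b-5p, miR403-5p, miR771 and miR777) had a median change in hasty that differed from that of 70 miRNAs of 21 nt by -0.28 on the log2 scale (exact permutation p = 0.015, adjusted p = 0.030), and by -0.40 to -0.21 when 1 of the 7 was left out. The hypothesis that 22-nt miRNAs respond differently to hasty may hold at a difference of -0.28, but it rests on 7 names. Of these, miR162a-5p, miR393b-5p and miR403-5p were the less abundant arms of their precursors, at means of 32.7, 67.8 and 15.1 counts. The more abundant arms were miR156a-3p and miR156c-3p. Length was therefore not separated from arm or level.

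The 52 miRNAs that start with U differed from 39 others by 0.060 (exact permutation p = 0.345, adjusted p = 0.395). The 8 miRNAs inside a coding gene on the same strand, miR781a among them, differed from 83 others by -0.060 (p = 0.395, exact permutation, adjusted p = 0.395).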
